A study of Mus musculus with 18 samples.

How the data were processed

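Total RNA of mouse ovaries was measured on Affymetrix Mouse Genome 430 2.0 arrays, 18 in 6 groups of 3 biological replicates: Pik3cd+/- and Pik3cd-/- females, each untreated, 44 hours after PMSG or 72 hours after the first of 3 injections of 0.03 ml E2 given 24 hours apart. The deposited values are intensity on a linear scale, 1 per probe set and array. The authors' notes name MAS5 without a version. The 2% trimmed means of the arrays ran from 210.1 to 223.7 and the replicate SD of the dimmest 20% of probe sets was 0.11 on the log2 scale, so the exact normalization is left open. The arrays had nearly the same distribution, and no further normalization was applied. The treated groups had no vehicle-injected counterpart among the 6 groups, so each treatment effect includes that of injection and of the hours that passed.

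Values were tested as log2 of the signal plus 8.58, the 10th percentile of all values, since their median (49.9) was under 50. A probe set was tested if at least 1 group mean lay above the median of 5.87. Of the probe sets, 64 controls, 9160 without a gene symbol and 932 with several were left out of the gene tests, and of the 34945 with 1 symbol the brightest stood for its gene, which gave 18193 genes and 12716 after the filter. A model of 6 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend on the mean level; 12 residual and 3.67 prior degrees of freedom). The 9 comparisons were the PMSG and E2 effects in each genotype, the genotype difference in each of the 3 states and the 2 interactions of treatment and genotype. All tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the 12716 genes, and genes with an adjusted p under 0.05 were called. The study's rule was applied to called genes with at least a 2-fold change. Overlaps of calls expected by chance are products of the counts. An average of the 3 genotype differences was added after the data were seen.

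The comparisons, tests, gene lists and rule for naming genes were set before the data were examined. The 26 lists were oocyte, immediate early, interferon response, macrophage, cell cycle, cholesterol synthesis, FSH-responsive granulosa, preantral granulosa, theca and steroidogenic, LH-responsive and cumulus expansion, luteal, PI3K pathway components, FoxO target, oestrogen target, apoptosis and atresia, glycolysis, proteases and inhibitors of the extracellular matrix, basal lamina, stromal fibroblast, smooth muscle, endothelial, lymphocyte, surface epithelium, oviduct, adipocyte and blood genes. Camera tested the 25 lists with at least 3 tested genes, with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Blood genes had 1 tested gene and were not analysed here. Of the list calls made with the preset correlation, those of LH-responsive and immediate early genes held with an estimated correlation for PMSG in Pik3cd+/- ovaries and for the genotype difference after PMSG, and no other call did. In every list called in the 9 comparisons the median, the mean and the test had the same sign. Several lists share genes (Star and Cyp11a1 are in 3), and most cell-type lists hold genes that other cells of the ovary also express. List members were matched by symbol or synonym.

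Genes named in a comparison were the 8 with the largest rise and the 8 with the largest fall among called genes whose single arrays did not overlap between the groups (genes with clone or provisional names left out), up to 4 members with the smallest adjusted p of each list called, and, for the treatment effects and interactions only, a panel of ovarian genes whatever their result. Chance alone gives no overlap in 10% of unchanged genes with 3 against 3 arrays. Of interactions, the 5 genes with the smallest p were named. Fewer list members were named where a comparison had many called lists, in the order of the rule, and none for the 7 lists with no member past the threshold after E2 in Pik3cd+/-, a choice made after the values were seen. H2-DMa, the MHC class II genes after PMSG and genes of the average genotype difference were chosen after their values were seen.

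Alternatives were a pseudocount of 1 or 64, no filter or one at the 70th percentile, quantile normalization, eBayes without trend, a model of only the groups of the comparison, the replicate number as a block (464 genes in the genotype difference after PMSG), the probe set with the highest variance, and each array left out in turn. The study's rule was also tried with a 2-fold change and no test. Leaving out 3 arrays together, and the block with only the groups of the comparison, were chosen after the data were seen. The labels do not state whether replicate numbers pair the arrays. Of simulated genes changed by log2 0.5, 1 and 2, the fit recovered 52.2%, 98.5% and 97.0% for PMSG against untreated. An interaction gave 22.4%, 77.6% and 98.5%. Power in the real arrays was not tested.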

Results

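Gene expression was measured in ovaries of 21-day-old female mice with 1 working copy of Pik3cd (Pik3cd+/-) or none (Pik3cd-/-), on a mixed C57B6J and S129 background. Pik3cd encodes p110 delta, a catalytic subunit of class I phosphoinositide 3-kinase. The mice were untreated, or were killed 44 hours after 10 IU of PMSG, a gonadotropin with FSH-like activity, or 72 hours after the first of 3 injections of oestradiol (E2). Each of the 6 groups held 3 arrays, 18 in all. Median signals per array lay between 48.4 and 50.9 intensity units, and the mean correlation of an array with its group mates lay between 0.969 and 0.993. The number of arrays limits the precision of every value. Changes are on the log2 scale ± SE of the model (3 arrays per group), signals are means ± SD (n = 3), and adjusted p-values (padj) for genes are from limma. For a gene list, the median log2 change is followed by the camera adjusted p and, after a slash, by that with an estimated correlation. Members of a list that passed with p adjusted over the list alone are counted as by list.

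The loss of Pik3cd was visible in the probe sets for the gene, of which there were 6. The clearest of them gave 67.1 ± 4.95 (SD, n = 3) in untreated Pik3cd+/- ovaries against 26.2 ± 2.52 in Pik3cd-/- ovaries. It gave 69.7 ± 2.08 against 23.5 ± 3.02 after PMSG and 70.4 ± 3.19 against 22.4 ± 4.59 after E2. The log2 differences were -1.12, -1.29 and -1.36 (limma, padj = 2.1e-04, 1.3e-05 and 1.1e-05). Another probe set was also lower in each state, at log2 -0.50, -0.41 and -0.73 (padj = 0.0237, 0.0266 and 6.4e-04). The brightest, which stood for the gene in the tests, did not pass in any state, at 0.22, -0.33 and 0.30 (padj = 0.499, 0.367 and 0.198 over all probe sets), so Pik3cd itself was not called. The remaining 3 did not pass either.

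**Figure D1:**
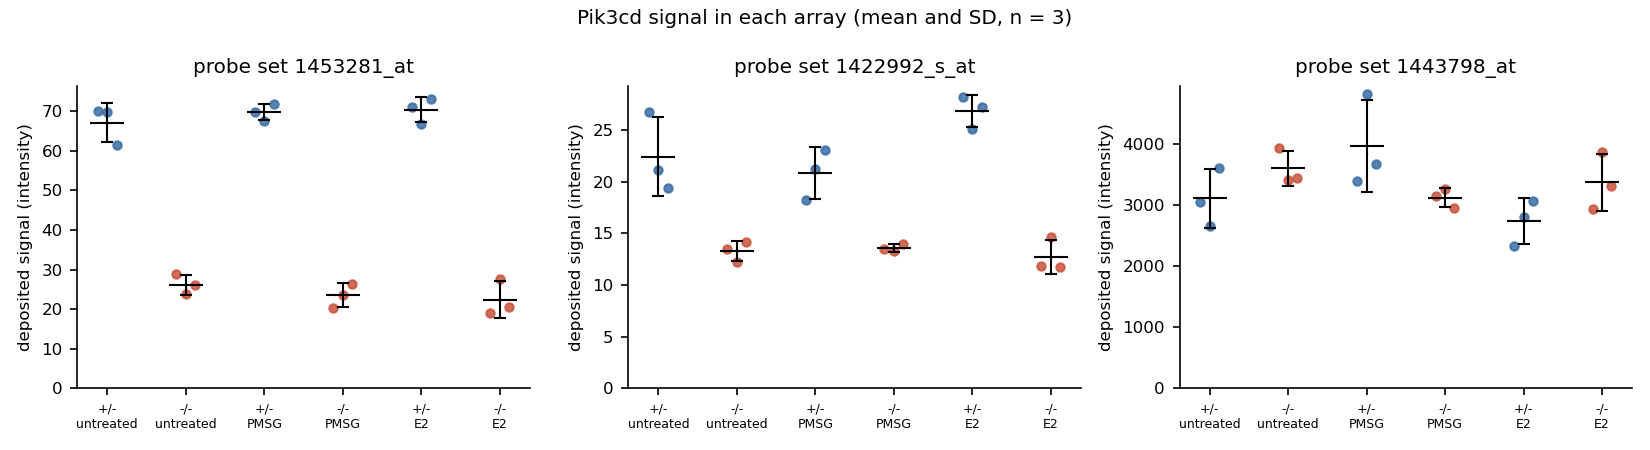
Deposited signal (intensity, linear axis from 0) of 3 Pik3cd probe sets in each array, by group; points are arrays, the black bar is the mean and the whiskers the SD (n = 3). In the left panel the Pik3cd-/- group means were 22.4 to 26.2 against 67.1 to 70.4 in Pik3cd+/-.

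The change after PMSG in Pik3cd+/- ovaries defined the study's PMSG target genes. Cyp17a1, the 17-hydroxylase of androgen synthesis, went from 466 ± 179 to 4204 ± 1398 (3.17 ± 0.61, padj = 0.00397). Cyp11a1, the cholesterol side-chain cleavage enzyme, went from 1339 ± 589 to 7318 ± 1591 (2.50 ± 0.46, padj = 0.00315). Star, which moves cholesterol into mitochondria, rose by 2.17 ± 0.56 (padj = 0.017). Fdx1, which passes electrons to Cyp11a1, rose by 1.60 ± 0.18 (padj = 2.1e-04). Among secreted factors, the BMP antagonist Grem1 rose by 3.12 ± 0.65 (padj = 0.00596) and the Wnt antagonist Sfrp4 by 2.59 ± 0.68 (padj = 0.0176). Other large rises were those of the matrix proteins Comp (2.72 ± 0.32, padj = 2.3e-04) and Spon1 (2.54 ± 0.42, padj = 0.00172). Next were the acute-phase protein Saa3 (2.49 ± 0.49, padj = 0.00466) and Rgs13 (2.42 ± 0.51, padj = 0.00602). The largest falls were those of Akr1c13 (-2.41 ± 0.62, padj = 0.017) and Pramel27 (-2.40 ± 0.73, padj = 0.0345). Next came Gfra2 (-1.77 ± 0.48, padj = 0.0204) and Nlrp4e (-1.74 ± 0.43, padj = 0.0136). B4galt6 fell by 1.65 ± 0.45, Cntn4 by 1.64 ± 0.28, Kazald1 by 1.60 ± 0.34 and Fndc5 by 1.60 ± 0.22 (padj = 0.0218, 0.00235, 0.00614 and 5.1e-04).

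Of the fixed lists, the oocyte genes fell together: 25 of 30, or 26 by list (-0.87, padj = 3.9e-13 / 0.246). Zp2 and Zp3, proteins of the zona pellucida, gave -0.91 ± 0.15 and -0.92 ± 0.16, the maternal-effect gene Nlrp5 -1.28 ± 0.22 and the transcription factor Nobox -0.97 ± 0.17 (padj = 0.00187, 0.00246, 0.00212 and 0.00257). Cell cycle genes also fell, 17 of 32, or 24 by list (-0.43, padj = 2.0e-08 / 0.308). The kinases Ttk (-0.69 ± 0.09, padj = 4.3e-04) and Bub1b (-0.64 ± 0.09, padj = 6.1e-04) were among them. Immediate early genes rose in 10 of 11, or 10 by list (0.70, padj = 2.2e-09 / 0.0134). The AP-1 genes Jun and Junb gave 0.92 ± 0.16 and 0.70 ± 0.12, the phosphatase Dusp1 1.07 ± 0.19 and Btg2 0.82 ± 0.15 (padj = 0.0021, 0.00225, 0.00252 and 0.00314). Cholesterol synthesis genes rose in 9 of 20, or 13 by list (0.54, padj = 6.1e-09 / 0.246). Cyp51 (0.79 ± 0.14, padj = 0.0022) and Sc5d (0.82 ± 0.14, padj = 0.00225) were among them. LH-responsive and cumulus expansion genes rose in 4 of 12, or 6 by list (0.73, padj = 6.7e-06 / 0.00761). The transcription factor Cebpb (0.99 ± 0.12, padj = 3.0e-04) and the protease Adamts1 (1.40 ± 0.19, padj = 4.2e-04) were among them.

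Members of the granulosa, theca and luteal lists went both ways. Of the theca and steroidogenic genes 7 rose and 3 fell of 15, 9 and 4 by list (0.42, padj = 0.00311 / 0.308). Gli1, a target of hedgehog signalling, was among the falls (-0.58 ± 0.09, padj = 8.3e-04). Of the FSH-responsive granulosa genes 4 rose and 2 fell of 17, 5 and 2 by list (0.33, padj = 0.00311 / 0.343). Of the luteal genes 4 rose and 2 fell of 12, 7 and 2 by list (0.84, padj = 0.00533 / 0.246). The tight-junction gene Cldn1 was among the falls (-1.41 ± 0.21, padj = 0.001). FoxO target genes rose in 5 of 20, or 5 by list (0.24, padj = 3.7e-05 / 0.246). Cited2 (0.81 ± 0.12, padj = 8.5e-04) and Pdk4 (1.70 ± 0.26, padj = 0.00104) were among them. Glycolysis genes rose in 5 of 15, or 9 by list (0.34, padj = 5.5e-05 / 0.246). Aldoa (0.40 ± 0.09, padj = 0.0106) and Pgam1 (0.43 ± 0.10, padj = 0.0123) were among them. Matrix proteases and their inhibitors rose in 5 of 17, or 5 by list (0.23, padj = 5.0e-04 / 0.246). Adamts5 (1.73 ± 0.21, padj = 2.7e-04) was among them.

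Markers of other cell types moved with the treatment as well. Macrophage genes rose in 5 of 17, or 10 by list (0.89, padj = 6.7e-07 / 0.343). The complement gene C1qa (1.29 ± 0.35, padj = 0.0213) and Aif1 (0.93 ± 0.26, padj = 0.0236) were among them. The list means of the 3 PMSG arrays were 8.59, 8.27 and 7.72. Smooth muscle genes rose in 2 of 10, or 2 by list (0.31, padj = 6.4e-04 / 0.343), desmin (Des, 1.32 ± 0.36, padj = 0.0219) and Actg2 (1.11 ± 0.36, padj = 0.0438). PMSG replicate 1 had the highest smooth muscle mean (10.64 against 10.27 and 10.32). Oviduct means were 8.31, 6.66 and 6.25 in the PMSG and 6.51, 8.44 and 6.83 in the untreated arrays. Interferon response genes rose in 2 of 10, or 2 by list (0.65, padj = 3.8e-04 / 0.343). Irf9 (0.66 ± 0.19, padj = 0.0254) and Oas1a (0.72 ± 0.21, padj = 0.0276) passed, while Ifit1 (1.09 ± 0.47, padj = 0.12) and Usp18 (1.02 ± 0.45, padj = 0.126) did not pass. Lists that did not pass included the PI3K pathway components (median -0.06, padj = 0.702), endothelial (-0.02, 0.702), lymphocyte (0.03, 0.664) and adipocyte genes (-0.11, 0.858). Preantral granulosa genes were at -0.01 (0.938), oestrogen targets at 0.08 (0.114) and apoptosis genes at 0.09 (0.378).

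In the panel of ovarian genes fixed beforehand, the FSH receptor gene Fshr rose (1.16 ± 0.30, padj = 0.0181). Ccnd2, a cyclin of granulosa proliferation (-0.43 ± 0.12, padj = 0.0275), Amh (-0.50 ± 0.13, padj = 0.0177) and the oocyte growth factor Gdf9 (-0.92 ± 0.17, padj = 0.00303) fell. Those that did not pass were Inhba (1.64 ± 0.66, padj = 0.0961), Pgr (0.88 ± 0.59, padj = 0.312) and Kit (-0.61 ± 0.21, padj = 0.0517). Nor did Esr1 (-0.44 ± 0.23, padj = 0.207) and Esr2 (-0.46 ± 0.15, padj = 0.0511). Inha (-0.06 ± 0.12), Kitl (-0.04 ± 0.14), Foxo1 (-0.0026 ± 0.15), Foxo3 (-0.21 ± 0.09) and Igf1 (-0.01 ± 0.20) did not pass either (padj = 0.758, 0.856, 0.993, 0.105 and 0.973). The aromatase and LH receptor genes of the panel were not analysed here. In all, limma called 2254 of 12716 genes, 739 higher and 1515 lower. Of these, 125 and 69 changed at least 2-fold. The count became 1166 and 1138 without Pik3cd+/- PMSG replicates 1 and 2, and 870 and 1164 without Pik3cd+/- untreated replicates 1 and 2. Of 49 calls named here, 17 ended when 1 array was left out: 10, 12 and 2 without PMSG replicates 1, 2 and 3, and 13, 12 and 9 without untreated replicates 1, 2 and 3, at adjusted p-values of up to 0.136 (Pramel27). Star, Sfrp4, Fshr and all named macrophage, smooth muscle and interferon genes were among these.

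**Figure D2:**
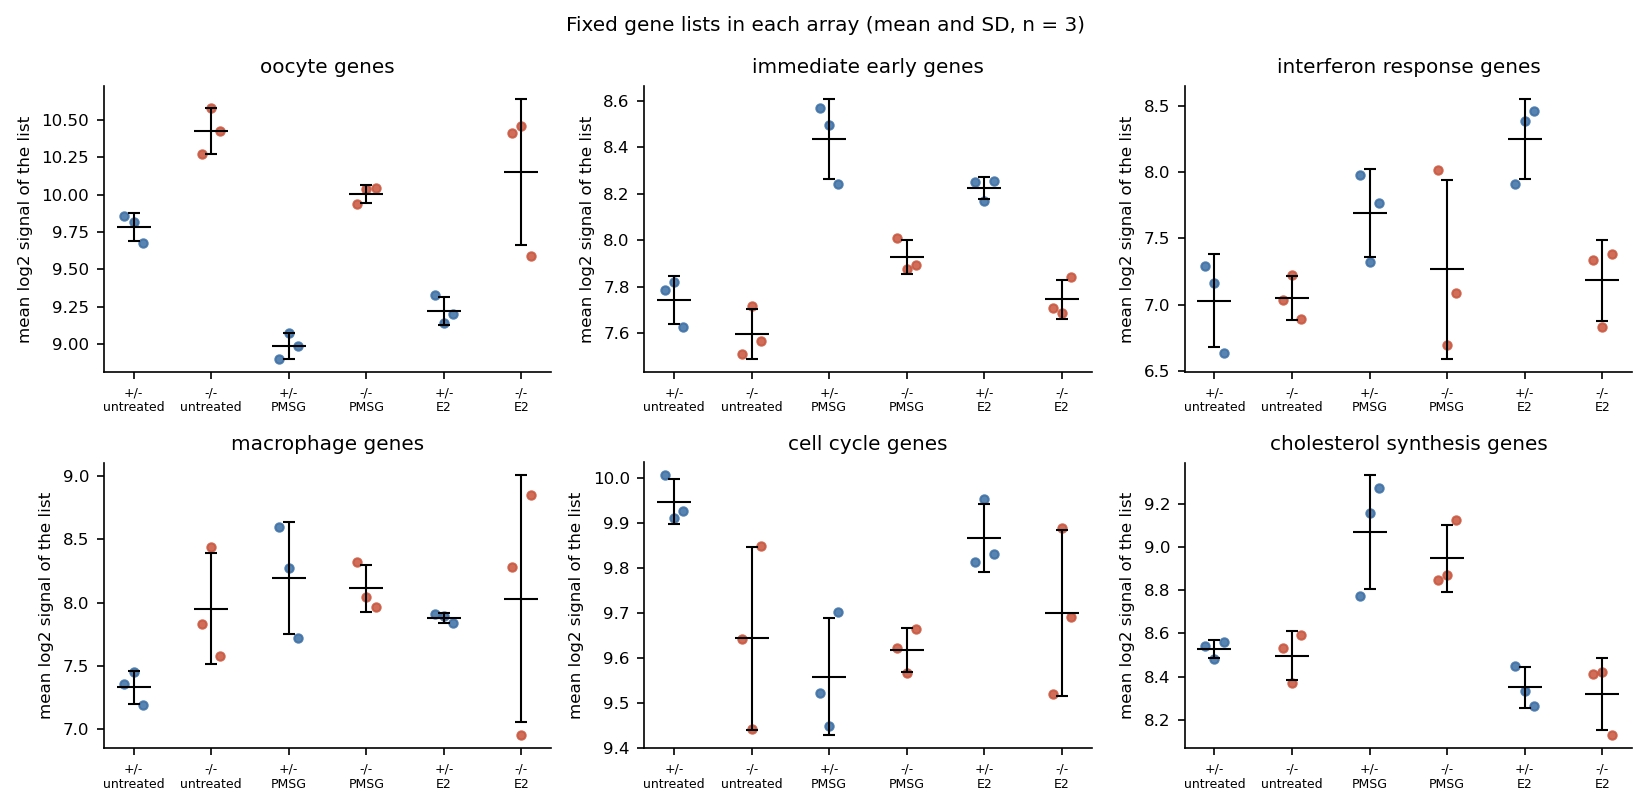
Mean log2 signal of 6 fixed gene lists (vertical axis) in each array, by group; points are arrays, the black bar is the mean and the whiskers the SD (n = 3), and the axes do not start at 0. The oocyte list fell by 0.87 (median log2 change) after PMSG in Pik3cd+/-, and the Pik3cd-/- E2 arrays spread widely for macrophage genes, from 6.95 to 8.85.

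The same treatment in Pik3cd-/- ovaries was set against the heterozygous response. Cyp17a1 went from 332 ± 290.3 to 4139.7 ± 1674 (3.87 ± 0.61, padj = 0.00387). Cyp11a1 went from 1099 ± 643 to 6801 ± 875 (2.76 ± 0.46, padj = 0.00595), with Fdx1 at 1.59 ± 0.18, padj = 3.1e-04. Fshr rose by 2.04 ± 0.30 (padj = 0.00287) and Grem1 by 2.63 ± 0.65 (padj = 0.0457). Rgs13 rose by 2.51 ± 0.51 (padj = 0.0174) and Saa3 by 2.15 ± 0.49 (padj = 0.0306). The dipeptidase Dpep1 (2.10 ± 0.25, padj = 4.0e-04) and the amino acid transporter Slc38a5 (2.07 ± 0.46, padj = 0.0251) completed the 8 largest rises. The largest falls were those of Igfbp3, a binding protein of insulin-like growth factors (-2.30 ± 0.44, padj = 0.014) and stanniocalcin Stc1 (-1.75 ± 0.33, padj = 0.0125). Next came Fmo2 (-1.37 ± 0.31, padj = 0.0287) and the lectin Mbl2 (-1.20 ± 0.26, padj = 0.0246). Adrenomedullin (Adm, -0.97 ± 0.22), Cldn1 (-0.92 ± 0.21), Pla2g1b (-0.92 ± 0.20) and Zg16 (-0.87 ± 0.21) fell as well (padj = 0.0269, 0.0329, 0.0228 and 0.0417).

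Theca and steroidogenic genes rose in 5 of 15, or 9 by list (0.61, padj = 2.0e-06 / 0.169). FSH-responsive granulosa genes rose in 2 of 17, or 5 by list (0.70, padj = 5.8e-07 / 0.179). Inhba (2.38 ± 0.66, padj = 0.0689) and Star (1.84 ± 0.56, padj = 0.0918) did not pass. Cholesterol synthesis genes rose in 3 of 20, or 10 by list (0.38, padj = 9.6e-09 / 0.179). Cyp51 (0.75 ± 0.14, padj = 0.00989) and Tm7sf2 (1.00 ± 0.21, padj = 0.0187) were among them. LH-responsive and cumulus expansion genes rose in 4 of 12, or 5 by list (0.37, padj = 0.0023 / 0.105). Cited1 (1.41 ± 0.18, padj = 6.3e-04) and Cebpb (0.78 ± 0.12, padj = 0.00399) were among them. Proteases and inhibitors rose in 4 of 17, or 6 by list, where 1 fell (0.21, padj = 3.3e-04 / 0.191). Cathepsin L (Ctsl, 0.49 ± 0.06, padj = 5.9e-04) and Adamts5 (1.51 ± 0.21, padj = 0.0015) were among them. Of the luteal genes 1 rose and 1 fell of 12, 5 and 1 by list (0.47, padj = 0.00464 / 0.179). The oocyte list was lower as a set with 0 of 30 members past the threshold, and 0 by list (-0.44, padj = 9.6e-09 / 0.308). Gpr3 (-0.33 ± 0.10), Ddx4 (-0.49 ± 0.16), Nobox (-0.50 ± 0.17) and Khdc3 (-0.51 ± 0.17) had padj = 0.098, 0.113, 0.132 and 0.133.

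Immediate early genes rose in 1 of 11, or 3 by list (0.30, padj = 1.5e-04 / 0.169). Nr4a1 passed (0.65 ± 0.16, padj = 0.0477), and Fos (0.91 ± 0.25, padj = 0.0689), Ier2 (0.30 ± 0.10, padj = 0.119) and Atf3 (0.30 ± 0.11, padj = 0.175) did not. Oestrogen target genes rose in 3 of 21, or 4 by list (0.03, padj = 0.0346 / 0.191). Susd3 (1.71 ± 0.23, padj = 0.00117) and Myc (0.66 ± 0.10, padj = 0.00292) were among them. This list call ended without Pik3cd-/- PMSG replicate 2 (padj = 0.0649) and without untreated replicates 2 and 3 (padj = 0.0899 and 0.103). Glycolysis genes were higher as a set, with 0 of 15 members past the threshold and 5 by list (0.22, padj = 2.9e-04 / 0.191). Pgam1 (0.37 ± 0.10, padj = 0.0691) and Ldha (0.33 ± 0.10, padj = 0.0955) came nearest. Macrophage (0.15, camera padj = 0.254) and cell cycle genes (-0.02, padj = 0.513) did not pass.

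Panel genes that did not pass were Inha (0.27 ± 0.12), Ccnd2 (0.16 ± 0.12), Esr1 (-0.51 ± 0.23), Esr2 (0.11 ± 0.15), Pgr (0.0081 ± 0.59), Amh (-0.17 ± 0.13) and Gdf9 (-0.31 ± 0.17), with adjusted p-values from 0.236 (Inha) to 0.996 (Pgr). Kitl (-0.30 ± 0.14), Kit (-0.21 ± 0.21), Foxo1 (0.13 ± 0.15), Foxo3 (-0.13 ± 0.09) and Igf1 (0.02 ± 0.20) had padj from 0.267 (Kitl) to 0.972 (Igf1). In all, 301 genes were called by limma, 215 higher and 86 lower. Of these, 49 and 4 changed at least 2-fold. The count became 117, 110 and 82 without Pik3cd-/- PMSG replicates 1, 2 and 3, and 139 and 187 without Pik3cd-/- untreated replicates 2 and 3. Of 26 calls named here, 15 ended with 1 array left out (10, 10 and 15 without PMSG replicates 1, 2 and 3, and 4, 12 and 7 without untreated replicates 1, 2 and 3; padj of up to 0.168, Nr4a1). Igfbp3, Stc1, Grem1 and Rgs13 were among these. Untreated Pik3cd-/- replicate 2 stood apart in the FSH-responsive list, with a mean of 9.34 against 10.31 and 10.21 in its group mates.

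**Figure D3:**
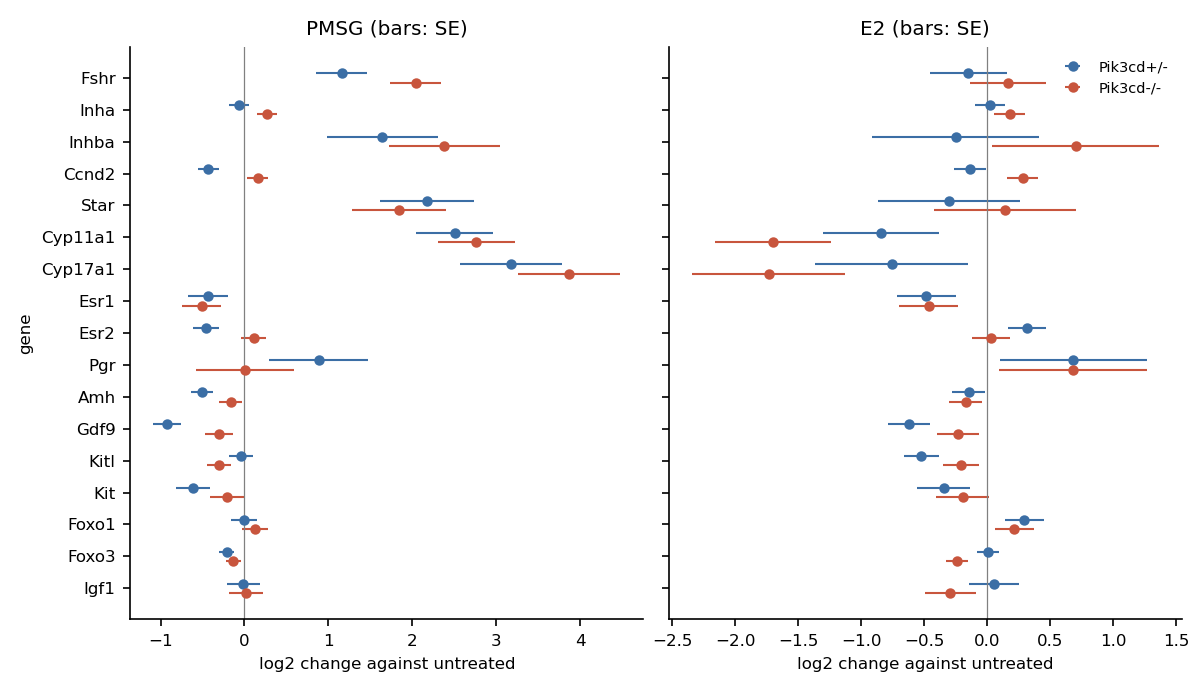
Log2 change against untreated ovaries (horizontal axis) of the 17 panel genes after PMSG (left) and E2 (right) in Pik3cd+/- and Pik3cd-/-; points are model estimates and bars the SE (3 arrays per group). Cyp17a1 and Cyp11a1 lay at 2.50 or more after PMSG in both genotypes.

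Side by side, the PMSG changes of the 12716 genes correlated between the genotypes (Pearson r = 0.638, Spearman 0.584, across genes, which are not independent replicates). Among genes called in both, 151 rose in both against 12.5 expected by chance, 50 fell in both against 10.2, and 0 went opposite ways. Among the genes called in Pik3cd+/-, the slope of the Pik3cd-/- change on the Pik3cd+/- change was 0.52, and 90.6% had the same sign. After E2 the correlation was 0.437 (Spearman 0.403), the slope 0.33 and the share with the same sign 82.4%, with 1 gene higher and 3 lower in both. Genes chosen in 1 genotype are expected to change less in the other. The reverse slopes, from genes called in Pik3cd-/-, were 0.87 after PMSG (301 genes) and 0.74 after E2 (7, too few to compare).

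E2 in Pik3cd+/- ovaries defined the E2 target genes. The antiviral gene Ifit1 went from 88.6 ± 40.9 to 359.6 ± 85.6 (1.98 ± 0.47, padj = 0.0471). Irf7, a transcription factor of the interferon response, went from 75.2 ± 24.6 to 225 ± 61.9 (1.49 ± 0.31, padj = 0.0279). Other large rises were those of Cd83 (1.98 ± 0.35, padj = 0.0135), the chitinase-like Chil3 (1.66 ± 0.28, padj = 0.00984) and Itih2 (1.65 ± 0.27, padj = 0.00899). Next were Rtp4 (1.56 ± 0.35, padj = 0.0363), netrin 4 (Ntn4, 1.55 ± 0.25, padj = 0.00824) and Fgd5 (1.37 ± 0.26, padj = 0.0162). Falls were led by the transcription factor Zbtb16 (-1.35 ± 0.25, padj = 0.0158) and Scara5 (-1.26 ± 0.30, padj = 0.0495). Next were Cldn1 (-1.24 ± 0.21, padj = 0.0112) and Aard (-1.20 ± 0.24, padj = 0.0223). The protocadherin Pcdh8 (-1.19 ± 0.24), the decoy receptor Il13ra2 (-1.11 ± 0.13), Nell1 (-1.09 ± 0.25) and Atp2b3 (-1.05 ± 0.18) also fell (padj = 0.0223, 0.00191, 0.0422 and 0.0115). Hsd3b1, an enzyme of steroid synthesis with a signal of 10185 ± 421 before treatment, fell to 5999 ± 1424 (-0.79 ± 0.13, padj = 0.00984).

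The interferon list rose in 5 of 10, or 9 by list (1.26, padj = 1.6e-09 / 0.28). Irf9 (0.85 ± 0.19, padj = 0.0336) and Oas1a (0.91 ± 0.21, padj = 0.0402) were also past the threshold. Immediate early genes rose in 4 of 11, or 7 by list (0.40, padj = 3.0e-07 / 0.0769). These were Jun (0.95 ± 0.16, padj = 0.00899), the orphan receptor Nr4a1 (0.89 ± 0.16, padj = 0.014), Btg2 (0.69 ± 0.15, padj = 0.032) and Atf3 (0.52 ± 0.11, padj = 0.0331). The oocyte list was lower as a set, with 1 of 30, or 25 by list (-0.61, padj = 1.4e-17 / 0.286). Nobox passed (-0.72 ± 0.17, padj = 0.044), and Nlrp5 (-0.88 ± 0.22, padj = 0.054), Khdc3 (-0.69 ± 0.17, padj = 0.0581) and Zp2 (-0.60 ± 0.15, padj = 0.0581) did not. Stromal fibroblast genes fell in 2 of 18, or 3 by list (-0.07, padj = 0.0318 / 0.743). These were the transcription factors Tcf21 (-0.53 ± 0.08, padj = 0.00641) and Nr2f2 (-0.41 ± 0.09, padj = 0.0331). FoxO targets rose in 1 of 20, or 2 by list (0.10, padj = 0.0153 / 0.53). This was the insulin receptor gene Insr (0.42 ± 0.10, padj = 0.0418), and Gadd45a came next (0.76 ± 0.20, padj = 0.0735). Basal lamina genes fell in 1 of 12, or 1 by list (-0.11, padj = 0.0335 / 0.564). This was Col18a1 (-0.50 ± 0.12, padj = 0.0471), and Lamb2 gave -0.28 ± 0.14, padj = 0.299. Theca and steroidogenic genes fell in 1 of 15, or 1 by list (-0.17, padj = 0.00804 / 0.522). Aldh1a1 (-0.45 ± 0.18, padj = 0.223) came after Hsd3b1. Luteal genes, which also hold Hsd3b1 and Cldn1, fell in 2 of 12, or 2 by list (-0.25, padj = 0.0162 / 0.435).

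Another 7 lists passed as sets with no member past the threshold, over all genes or by list. Higher were macrophage (0.55, padj = 8.0e-04 / 0.565) and smooth muscle genes (0.30, padj = 0.0153 / 0.565). So were glycolysis (0.10, padj = 0.0153 / 0.545) and apoptosis and atresia genes (0.15, padj = 0.0335 / 0.28). Lower were cholesterol synthesis (-0.18, padj = 0.0153 / 0.565), cell cycle (-0.07, padj = 0.0186 / 0.743) and oviduct genes (-0.67, padj = 0.0153 / 0.53). Untreated Pik3cd+/- replicate 2 had an oviduct list mean of 8.44 against 6.51 and 6.83 in its mates, and the oviduct call ended without it (padj = 0.118) and without E2 replicate 1 (0.0872). Without E2 replicate 1 the calls of apoptosis (0.0872), basal lamina (0.112), cell cycle (0.158) and stromal genes (0.11) ended too. Without untreated replicate 3 the adjusted p-values were 0.0656 for cholesterol, glycolysis, theca and apoptosis genes, 0.0941 for basal lamina, 0.0525 for cell cycle, 0.0503 for luteal and 0.0734 for stromal genes. Without untreated replicate 1 that of cell cycle genes was 0.0568, and without replicate 2 that of apoptosis genes 0.0724.

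None of the 17 panel genes passed. Cyp11a1 (-0.84 ± 0.46), Cyp17a1 (-0.76 ± 0.61), Star (-0.30 ± 0.56), Fshr (-0.15 ± 0.30), Inha (0.02 ± 0.12), Inhba (-0.25 ± 0.66), Ccnd2 (-0.14 ± 0.12), Esr1 (-0.48 ± 0.23) and Esr2 (0.32 ± 0.15) had padj from 0.308 (Esr2) to 0.96 (Inha). Gdf9 (-0.62 ± 0.17), Kitl (-0.52 ± 0.14), Pgr (0.68 ± 0.59), Amh (-0.15 ± 0.13), Kit (-0.35 ± 0.21), Foxo1 (0.29 ± 0.15), Foxo3 (0.009 ± 0.09) and Igf1 (0.05 ± 0.20) had padj from 0.0722 (Gdf9) to 0.976 (Foxo3). In all, 205 genes were called, 149 higher and 56 lower, with 29 and 8 changed at least 2-fold. The share lower, 27.3%, was 52.1% of 771 genes in a model of these 6 arrays alone. Each of the 6 arrays moved the count: it was 79, 49 and 110 without E2 replicates 1, 2 and 3, and 83, 103 and 33 without untreated replicates 1, 2 and 3. Of 28 calls named here, 24 ended with 1 array left out (13, 20 and 13 without E2 replicates 1, 2 and 3, and 19, 12 and 23 without untreated replicates 1, 2 and 3; padj of up to 0.205, Ifit1). Those of Il13ra2, Tcf21, Ntn4 and Jun were kept in these fits. The 3'/5' signal ratio of GAPDH, a sign of RNA quality, was higher after E2 with no overlap, at 0.866 ± 0.039 (SD, n = 3) against 0.813 ± 0.009, and that of actin was 1.41 ± 0.11 against 1.33 ± 0.02.

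In Pik3cd-/- ovaries the smallest adjusted p after E2 was that of Chil3, which went from 11.8 ± 0.564 to 92.6 ± 36.6 (2.23 ± 0.28, padj = 0.00886). The untreated signal lay near the 10th percentile of all values (8.58), and the size of the change depended on the pseudocount (2.78 with 1, 1.02 with 64). Falling genes were Prss35 (-1.09 ± 0.18, padj = 0.0365) and Susd4 (-0.80 ± 0.12, padj = 0.0343). So were Osr2 (-0.65 ± 0.11, padj = 0.0365), Adamts9 (-0.60 ± 0.10, padj = 0.0343) and Hsp90aa1 (-0.51 ± 0.08, padj = 0.0343). As sets, FSH-responsive granulosa (0.26, padj = 0.0445 / 0.831) and immediate early genes (0.11, padj = 0.0365 / 0.831) were higher. Oocyte (-0.30, padj = 0.0036 / 0.831), basal lamina (-0.19, padj = 0.0445 / 0.831) and stromal fibroblast genes (-0.29, padj = 0.0059 / 0.831) were lower. No member of these 5 lists passed over all genes. By list, 1 FSH-responsive, 2 basal lamina and 3 stromal genes fell, 2 immediate early genes rose and 1 fell, and the oocyte list had 0. Members nearest to the threshold were Nr4a1 (0.77 ± 0.16, padj = 0.128), Atf3 (0.51 ± 0.11, padj = 0.149), Egr1 (-0.64 ± 0.22, padj = 0.251) and Fos (0.59 ± 0.25, padj = 0.312) of the immediate early genes. Of the other lists they were Vegfa (0.47 ± 0.15, padj = 0.238) and Cyp11a1 (-1.70 ± 0.46, padj = 0.213) of the FSH-responsive genes, Col18a1 (-0.47 ± 0.12, padj = 0.204) and Lamb2 (-0.44 ± 0.14, padj = 0.231), and Pdgfra (-0.63 ± 0.16, padj = 0.185) and Nr2f2 (-0.34 ± 0.09, padj = 0.209). Nobox (-0.45 ± 0.17, padj = 0.274), Sohlh2 (-0.35 ± 0.14, padj = 0.278), Padi6 (-0.42 ± 0.17, padj = 0.293) and Ooep (-0.45 ± 0.19, padj = 0.299) were those of the oocyte list.

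The 3 Pik3cd-/- E2 arrays differed from each other in markers of other cell types. Adipocyte list means were 9.37, 5.93 and 10.93 in replicates 1, 2 and 3, and macrophage means 8.28, 6.95 and 8.85. Stromal means were 11.01, 10.30 and 11.40, and oocyte means 10.41, 10.46 and 9.59. Without E2 replicate 3 the oocyte median became 0.02 (padj = 0.27), and the FSH-responsive (0.296) and immediate early (0.112) calls ended. Without E2 replicate 2 the stromal median became -0.01, its test turned to higher (padj = 0.998), and the basal lamina (0.173) and FSH-responsive (0.179) calls ended. Basal lamina genes also lost the call without E2 replicate 1 (0.17) and untreated replicate 1 (0.52). Stromal genes (0.212) and immediate early genes (0.212) lost it without untreated replicate 1, immediate early genes without untreated replicate 3 (0.11), and FSH-responsive genes without untreated replicate 2 (0.998, median -0.07). Without that array and E2 replicates 2 and 3, FSH-responsive genes were called lower (-0.46, padj = 4.1e-06). No panel gene passed. Cyp17a1 (-1.74 ± 0.61), Star (0.14 ± 0.56), Fshr (0.17 ± 0.30), Inha (0.18 ± 0.12), Inhba (0.70 ± 0.66), Ccnd2 (0.28 ± 0.12), Esr1 (-0.46 ± 0.23) and Esr2 (0.03 ± 0.15) had padj from 0.257 (Cyp17a1) to 0.938 (Esr2). Pgr (0.68 ± 0.59), Amh (-0.17 ± 0.13), Gdf9 (-0.23 ± 0.17), Kitl (-0.21 ± 0.14), Kit (-0.20 ± 0.21), Foxo1 (0.22 ± 0.15), Foxo3 (-0.24 ± 0.09) and Igf1 (-0.29 ± 0.20) had padj from 0.268 (Foxo3) to 0.654 (Kit). In all, limma called 7 genes, 1 higher and 6 lower, with 1 each at 2-fold. The count was 3 and 2 without Pik3cd-/- E2 replicates 1 and 3, and 3, 3 and 24 without untreated replicates 1, 2 and 3. Of 6 calls named here, 5 ended with 1 array left out (4, 4 and 5 without E2 replicates 1, 2 and 3, and 5 and 4 without untreated replicates 1 and 2; padj of up to 0.246, Osr2). That of Chil3 was kept in these fits and ended in a model of these 6 arrays alone (padj = 0.718).

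Untreated Pik3cd-/- ovaries were compared with untreated Pik3cd+/- ovaries for the state before stimulation. The 3'/5' signal ratio of actin, a sign of RNA quality, did not overlap between them, at 1.39 ± 0.04 (SD, n = 3) against 1.33 ± 0.02. Among the genes higher, Sycp3, of the meiotic synaptonemal complex, was at 711 ± 199 against 226 ± 69.5 (1.63 ± 0.26, padj = 0.0164). The germ cell helicase Ddx4 was at 383 ± 21.2 against 173 ± 18.7 (1.11 ± 0.16, padj = 0.00782). Of genes of antigen presentation by MHC class II, H2-Aa (1.89 ± 0.38, padj = 0.0274), H2-Eb1 (1.51 ± 0.32, padj = 0.0287), H2-Ab1 (1.39 ± 0.31, padj = 0.0348) and the invariant chain Cd74 (1.54 ± 0.36, padj = 0.0409) were higher. H2-DMa did not pass (0.43 ± 0.18, padj = 0.195). Phospholamban (Pln, 1.60 ± 0.31, padj = 0.0264), Mtmr7 (1.34 ± 0.27, padj = 0.0274) and the oocyte transcription factor Sohlh1 (1.26 ± 0.28, padj = 0.0318) followed. Lower were the amino acid transporters Slc38a5 (-2.28 ± 0.46, padj = 0.0274) and Slc6a15 (-1.55 ± 0.36, padj = 0.0376). So were the endopeptidase Phex (-1.95 ± 0.38, padj = 0.0274) and the apolipoprotein Apoa4 (-1.59 ± 0.36, padj = 0.0363). Gsta2 (-1.51 ± 0.30), Sel1l3 (-1.49 ± 0.28), Lrrc2 (-1.47 ± 0.36) and Tex14 (-1.44 ± 0.33) were lower too (padj = 0.0274, 0.0251, 0.0477 and 0.0376).

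The oocyte list was higher, with 10 of 30, or 25 by list (0.62, padj = 6.0e-19 / 0.819). Zp2 (0.86 ± 0.15, padj = 0.0193), Dppa3 (0.92 ± 0.18, padj = 0.0274) and Sohlh2 (0.67 ± 0.14, padj = 0.0274) stood beside Ddx4. Cell cycle genes were lower, 1 of 32, or 13 by list (-0.29, padj = 1.7e-07 / 0.819). The replication licensing gene Mcm7 passed (-0.31 ± 0.08, padj = 0.0476), and the mitotic cyclin Ccnb2 was just short of it (-0.66 ± 0.17, padj = 0.0503). Surface epithelium genes were higher, 1 of 10, or 1 by list (0.44, padj = 8.7e-04 / 0.819). Lgr5 passed (1.19 ± 0.24, padj = 0.0274), and Krt19 came next (0.89 ± 0.31, padj = 0.12). Macrophage (0.58, padj = 1.3e-04 / 0.819) and smooth muscle genes (0.33, padj = 0.0148 / 0.819) were higher as sets with no member past the threshold, over all genes or by list. Aif1 (0.69 ± 0.26, padj = 0.155), Ctss (0.90 ± 0.35, padj = 0.166), Synpo2 (0.69 ± 0.33, padj = 0.244) and Des (0.76 ± 0.36, padj = 0.253) came nearest. The smooth muscle call ended without Pik3cd-/- untreated replicate 1 (padj = 0.0765). In all, 277 genes were called, 107 higher and 170 lower in Pik3cd-/-, with 23 and 27 at least 2-fold. The share lower, 61.4%, was 36.9% and 77.0% without Pik3cd-/- replicates 1 and 3, 20% and 77.5% without Pik3cd+/- replicates 1 and 3, and 41.1% in a model of these 6 arrays alone. The count was 4 and 677 without Pik3cd-/- untreated replicates 2 and 3, and 20, 1 and 89 without Pik3cd+/- untreated replicates 1, 2 and 3. All 22 calls named here ended with 1 array left out. They were 7, 21 and 1 without Pik3cd-/- replicates 1, 2 and 3, and 17, 22 and 16 without Pik3cd+/- replicates 1, 2 and 3, at adjusted p of up to 0.205 (Mcm7). Replicate 2 of untreated Pik3cd-/- had the lowest FSH-responsive list mean of its group (9.34) and the highest macrophage mean (8.44 against 7.84 and 7.58).

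After PMSG the oocyte genes again stood out as higher in Pik3cd-/- ovaries. Nlrp5 was at 2643 ± 516 against 798 ± 134 (1.71 ± 0.22, padj = 0.00138). Zp2 was at 2409 ± 233 against 884 ± 88.8 (1.44 ± 0.15, padj = 4.5e-04). The oocyte-expressed genes Ooep (1.37 ± 0.19, padj = 0.00169), Padi6 (1.36 ± 0.17, padj = 0.00138) and the egg protease Astl (1.38 ± 0.23, padj = 0.00604) followed. Next came Dppa5a (1.38 ± 0.18, padj = 0.00138), Mael, of the germ cell piRNA pathway (1.37 ± 0.25, padj = 0.0093), and Ccdc201 (1.34 ± 0.18, padj = 0.00169). Lower were Asb4 (96.7 ± 19.4 against 449.9 ± 123; -2.11 ± 0.17, padj = 3.0e-05) and the AP-1 gene Fos (-1.68 ± 0.25, padj = 0.00308). Also lower were Bmp2, a growth factor of granulosa cells (-1.63 ± 0.23, padj = 0.00224), and the myogenic factor Myf5 (-1.62 ± 0.25, padj = 0.00396). Nlrp10 (-1.54 ± 0.25), Mug1 (-1.46 ± 0.31), Mlf1 (-1.45 ± 0.27) and Grb14, an adaptor that binds the insulin receptor (-1.37 ± 0.23), were lower too (padj = 0.00589, 0.0166, 0.00864 and 0.00628).

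Of the oocyte list, 25 of 30, or 30 by list, were higher (1.03, padj = 1.5e-33 / 0.0779), Zp3 among them (1.24 ± 0.16, padj = 0.0014). Immediate early genes were lower in 3 of 11, or 6 by list (-0.45, padj = 3.7e-07 / 0.0368). Fos, Junb (-0.62 ± 0.12, padj = 0.0113) and Egr2 (-0.71 ± 0.16, padj = 0.0266) passed and Jun did not (-0.55 ± 0.16, padj = 0.0593). LH-responsive and cumulus expansion genes were lower as a set, 0 of 12, or 6 by list (-0.48, padj = 4.6e-05 / 0.0133). Ptx3, of the cumulus matrix (-0.44 ± 0.12, padj = 0.0552), and Egr1 (-0.70 ± 0.22, padj = 0.0916) came nearest. FoxO targets were lower in 4 of 20, or 4 by list (-0.20, padj = 4.6e-05 / 0.236). Irs2 (-0.57 ± 0.11, padj = 0.0107) and Gadd45a (-0.94 ± 0.20, padj = 0.0203) were among them. Glycolysis genes were lower in 1 of 15, or 3 by list (-0.16, padj = 7.6e-04 / 0.488). This was Pfkp (-0.61 ± 0.14, padj = 0.0248), with Ldha next (-0.37 ± 0.10, padj = 0.0522). The list call ended without Pik3cd+/- PMSG replicate 3 (padj = 0.0634). Interferon genes were lower as a set with 0 of 10 past the threshold and 0 by list (-0.41, padj = 0.0181 / 0.913). Irf9 (-0.41 ± 0.19, padj = 0.267), Usp18 (-0.92 ± 0.45, padj = 0.301), Oasl2 (-0.53 ± 0.33, padj = 0.448) and Ifit1 (-0.71 ± 0.47, padj = 0.478) did not pass. The call ended without Pik3cd-/- PMSG replicate 2 (median -0.16, 0.365) and 3 (-0.30, 0.072) and Pik3cd+/- PMSG replicate 1 (-0.33, 0.173).

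In all, 526 genes were called after PMSG, 393 higher and 133 lower in Pik3cd-/-, with 60 and 32 at least 2-fold. The count was 260, 82 and 164 without Pik3cd-/- PMSG replicates 1, 2 and 3, and 141 and 203 without Pik3cd+/- PMSG replicates 1 and 2. Of 22 calls named here, 7 ended with 1 array left out (1, 7 and 3 without Pik3cd-/- replicates 1, 2 and 3, and 4, 3 and 1 without Pik3cd+/- replicates 1, 2 and 3; padj of up to 0.102, Egr2). These were Mlf1, Irs2, Junb, Mug1, Gadd45a, Pfkp and Egr2. Arrays of the same replicate number resembled each other across the genotypes in this comparison only (r = 0.25, 0.25 and 0.30). With the replicate number as a block the count was 464 over all groups and 1067 over the PMSG groups alone, the latter chosen after the data were seen; in it Jun, Egr1 and Usp18 passed too.

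After E2, Usp18, which restrains interferon signalling, was lower in Pik3cd-/- ovaries, at 72.9 ± 24.8 against 322 ± 68.1 (-2.04 ± 0.45, padj = 0.0101). Ifit1 was at 101 ± 40.2 against 359.6 ± 85.6 (-1.79 ± 0.47, padj = 0.0208). Also lower were Slc38a5 (-1.98 ± 0.46, padj = 0.0121), Itih2 (-1.96 ± 0.27, padj = 0.00122) and Rgs13 (-1.83 ± 0.51, padj = 0.0249). So were Fgd5 (-1.77 ± 0.26, padj = 0.00176), Myf5 (-1.61 ± 0.25, padj = 0.0019) and Fos (-1.60 ± 0.25, padj = 0.00198). The largest rises over Pik3cd+/- were those of Sycp3 (1.63 ± 0.26, padj = 0.00199) and Ddx4 (1.56 ± 0.16, padj = 3.7e-04). Next were Pramel29 (1.55 ± 0.23, padj = 0.00176) and Calb1 (1.53 ± 0.44, padj = 0.0287). Kdf1 (1.52 ± 0.22), Mael (1.52 ± 0.25), Khdc1a (1.46 ± 0.17) and Pln (1.43 ± 0.31) were higher too (padj = 0.00176, 0.0027, 5.4e-04 and 0.00926).

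All 30 of 30 oocyte genes tested were higher, as were 30 by list (0.93, padj = 1.4e-26 / 0.444). Zp2 (1.13 ± 0.15, padj = 0.00112), Zp3 (1.17 ± 0.16, padj = 0.00122) and Nlrp5 (1.43 ± 0.22, padj = 0.00176) were among them. Interferon genes were lower in 8 of 10, or 8 by list (-1.15, padj = 0.00581 / 0.865). Rsad2 (-1.18 ± 0.28, padj = 0.0141), Irf9 (-0.78 ± 0.19, padj = 0.0148) and Oasl2 (-1.27 ± 0.33, padj = 0.019) were among them. Immediate early genes were lower in 5 of 11, or 8 by list (-0.39, padj = 0.0124 / 0.686). Jun (-0.77 ± 0.16, padj = 0.00654), Egr1 (-0.93 ± 0.22, padj = 0.0135) and Egr2 (-0.58 ± 0.16, padj = 0.0262) were among them. Without Pik3cd+/- E2 replicate 3 the interferon (padj = 0.0691) and immediate early (0.0762) calls ended. Glycolysis genes were lower in 4 of 15, or 6 by list (-0.27, padj = 0.007 / 0.865). Pfkp (-0.89 ± 0.14, padj = 0.0019) and Hk2 (-0.53 ± 0.10, padj = 0.00554) were among them. Surface epithelium genes were higher in 2 of 10, or 2 by list (0.31, padj = 0.0124 / 0.865). These were Bnc1 (0.84 ± 0.21, padj = 0.0157) and Lgr5 (0.93 ± 0.24, padj = 0.0192). This call ended without Pik3cd-/- E2 replicates 1 and 3 (0.0832 and 0.129) and Pik3cd+/- E2 replicate 1 (0.0549). In all, 2139 genes were called, 616 higher and 1523 lower in Pik3cd-/-, with 53 and 76 at least 2-fold. The share lower, 71.2%, was 56.2% with quantile normalization, 58.0% without Pik3cd-/- E2 replicate 3 and 45.3% without 3 Pik3cd-/- arrays (untreated replicate 2, E2 replicates 2 and 3). The count was 647 and 1274 without Pik3cd-/- E2 replicates 1 and 2, 748 and 793 without Pik3cd+/- E2 replicates 1 and 2, and 100 in a model of the 6 E2 arrays alone. Of 29 calls named here, 11 ended with 1 array left out (7 each without Pik3cd-/- replicates 1 and 2, and 5, 7 and 2 without Pik3cd+/- replicates 1, 2 and 3; padj of up to 0.116, Calb1). Slc38a5, Rgs13, Ifit1, Irf9, Rsad2 and Oasl2 were among these. The Pik3cd-/- E2 arrays spread in cell-type markers as above. The 3'/5' ratio of GAPDH was 0.866 ± 0.039 (SD, n = 3) in Pik3cd+/- and 0.793 ± 0.026 in Pik3cd-/- E2 arrays, and that of actin 1.41 ± 0.11 and 1.45 ± 0.03. Pik3cd+/- E2 replicate 3 had the highest ratios of the 18 arrays (0.908 and 1.53).

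The genotype differences of the 3 states overlapped. Higher in Pik3cd-/- in all 3 were 50 genes and lower 21, against 0.16 and 0.21 expected by chance. The differences correlated across genes at r = 0.474 between untreated and PMSG, 0.644 between untreated and E2, and 0.599 between PMSG and E2, and 1 gene was called in opposite directions in a pair of states. Genes near Pik3cd on its chromosome were not called more often: of 116 tested genes within 200 places on either side, 19 (16.4%) were called in any state against 2406 of 12599 elsewhere (19.1%; odds ratio 0.83, 95% interval 0.478 to 1.37, Fisher's exact test, two-sided p = 0.553).

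**Figure D4:**
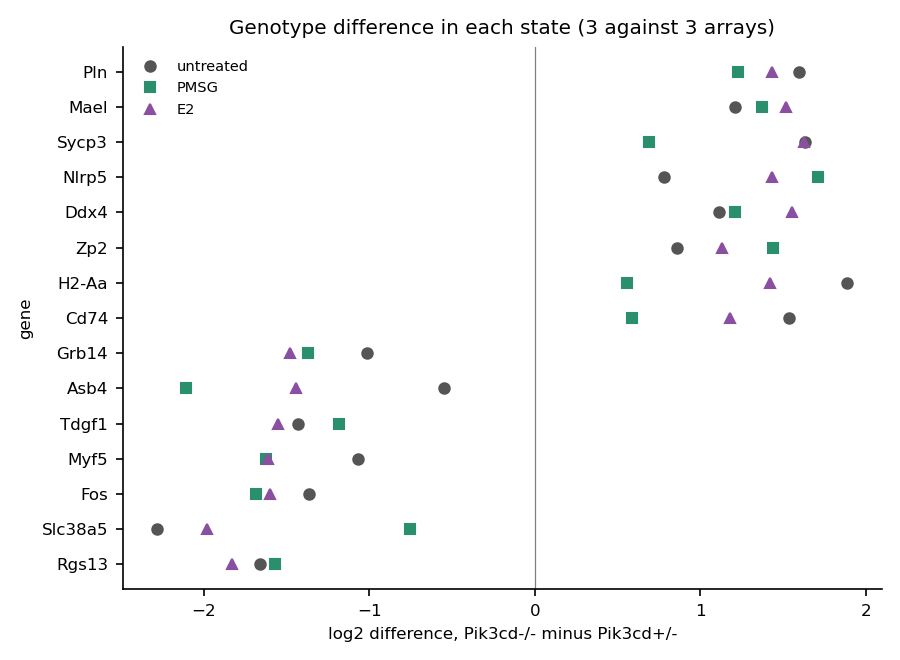
Log2 difference of Pik3cd-/- minus Pik3cd+/- (horizontal axis) for 15 genes in untreated, PMSG and E2 ovaries. Each point is a model estimate from 3 against 3 arrays. Most genes were chosen for the same sign in each state, which all have. Sycp3 was at 1.63 untreated and Asb4 at -2.11 after PMSG.

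Whether the response to PMSG itself differed between the genotypes was tested as an interaction, the Pik3cd-/- change minus the Pik3cd+/- change. Limma called 0 of 12716 genes, with 1196 at unadjusted p under 0.05 (chance 635.8). The smallest p-values were those of Ddhd1 (1.31 ± 0.20, padj = 0.0711), and Asb4 (-1.56 ± 0.25, padj = 0.0711). Next were Pawr (-0.65 ± 0.11, padj = 0.112), Lrp11 (-1.52 ± 0.27, padj = 0.121) and Slc25a42 (0.92 ± 0.17, padj = 0.153). Without Pik3cd-/- PMSG replicate 1 the count was 1, and without Pik3cd+/- PMSG replicate 3 it was 4. Of the lists, 10 differed as sets, none of them with an estimated correlation. More positive in Pik3cd-/- were cell cycle (0.35, padj = 3.1e-10 / 0.363), oocyte (0.39, padj = 1.9e-05 / 0.752) and preantral granulosa genes (0.23, padj = 0.0347 / 0.271). More negative were macrophage (-0.69, padj = 2.5e-06 / 0.638) and FoxO target genes (-0.38, padj = 8.1e-07 / 0.138). So were immediate early (-0.34, padj = 1.9e-05 / 0.138) and smooth muscle genes (-0.45, padj = 5.0e-05 / 0.552). Interferon response (-0.41, padj = 0.00634 / 0.752), LH-responsive (-0.24, padj = 0.0208 / 0.138) and surface epithelium genes (-0.31, padj = 0.0491 / 0.812) were more negative too. No member passed over all genes; by list, 3 of 32 cell cycle genes and 1 of 20 FoxO targets did, and 0 of the other 8 lists.

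Members of these lists with the smallest adjusted p were Bub1b (0.61 ± 0.13, padj = 0.244), Cited2 (-0.67 ± 0.17, padj = 0.348), Nlrp5 (0.93 ± 0.31, padj = 0.402) and Ooep (0.72 ± 0.26, padj = 0.419). Next were Dusp1 (-0.72 ± 0.27, padj = 0.422), Junb (-0.45 ± 0.17, padj = 0.433) and Aif1 (-0.90 ± 0.37, padj = 0.468). Lmod1 (-0.32 ± 0.14), Irf9 (-0.42 ± 0.27), Ifih1 (-0.60 ± 0.39), Ptx3 (-0.49 ± 0.17), Krt19 (-0.74 ± 0.43) and Esr2 (0.56 ± 0.22) had padj = 0.506, 0.642, 0.644, 0.418, 0.606 and 0.44. The calls of preantral genes (without Pik3cd-/- PMSG replicate 2, 0.0672; Pik3cd-/- untreated replicate 2, 0.233; Pik3cd+/- PMSG replicate 2, 0.0537; Pik3cd+/- untreated replicate 3, 0.0954) and interferon genes (Pik3cd-/- PMSG replicate 2, 0.177; Pik3cd+/- untreated replicate 3, 0.0713) ended with 1 array left out. The surface epithelium call ended without Pik3cd-/- PMSG replicates 1 and 3 (0.0543 and 0.201), Pik3cd-/- untreated replicate 2 (0.324), Pik3cd+/- PMSG replicates 1 and 2 (0.243 and 0.0878) and Pik3cd+/- untreated replicates 1 and 3 (0.0861 and 0.0534). It also ended with the stricter filter (-0.18, 0.274), no filter (0.0726), the highest-variance probe set (0.0557), a pseudocount of 64 (0.0508), quantile normalization (0.0545) and the replicate block (0.0522). Panel genes did not pass. Ccnd2 (0.59 ± 0.18), Gdf9 (0.61 ± 0.23), Fshr (0.88 ± 0.43), Amh (0.34 ± 0.19), Inha (0.33 ± 0.17), Inhba (0.74 ± 0.93), Star (-0.33 ± 0.79), Cyp11a1 (0.26 ± 0.65) and Cyp17a1 (0.70 ± 0.86) had padj from 0.359 (Ccnd2) to 0.927 (Cyp11a1). Esr1 (-0.07 ± 0.33), Pgr (-0.87 ± 0.83), Kitl (-0.25 ± 0.20), Kit (0.41 ± 0.29), Foxo1 (0.13 ± 0.22), Foxo3 (0.08 ± 0.12) and Igf1 (0.03 ± 0.28) had padj from 0.683 (Kit) to 0.984 (Igf1).

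In limma the E2 interaction had 0 calls, with 923 at unadjusted p under 0.05 (chance 635.8). The smallest p-values were those of Coq8a (-0.80 ± 0.13, padj = 0.25), and Itih2 (-2.12 ± 0.38, padj = 0.306). Next were Ddhd1 (1.06 ± 0.20, padj = 0.309), Stox2 (0.75 ± 0.16, padj = 0.386) and Ntn4 (-1.65 ± 0.35, padj = 0.386). Without Pik3cd-/- E2 replicate 3 the count was 71. As sets, 7 lists differed, none with an estimated correlation. Interferon response (-1.08, padj = 6.1e-06 / 0.591), smooth muscle (-0.59, padj = 9.7e-04 / 0.591), FoxO target (-0.23, padj = 0.00152 / 0.591) and immediate early genes (-0.25, padj = 0.00663 / 0.591) were more negative in Pik3cd-/-. Oocyte (0.30, padj = 1.8e-07 / 0.591), FSH-responsive (0.26, padj = 0.00152 / 0.591) and cell cycle genes (0.10, padj = 8.8e-05 / 0.591) were more positive. By list, 8 of 10 interferon, 5 of 20 FoxO target and 2 of 11 immediate early genes passed, and 0 of the other 4 lists; over all genes 0 did. Rsad2 (-1.34 ± 0.40, padj = 0.544), Irf9 (-0.78 ± 0.27, padj = 0.612), Insr (-0.58 ± 0.14, padj = 0.386), Btg2 (-0.78 ± 0.21, padj = 0.508), Jun (-0.78 ± 0.22, padj = 0.508) and Nlrp14 (0.60 ± 0.25, padj = 0.671) were their nearest members. Nlrp5 (0.65 ± 0.31), Mcm4 (0.38 ± 0.15), Acta2 (-0.28 ± 0.12) and Ccnd2 (0.42 ± 0.18) followed (padj = 0.683, 0.659, 0.671 and 0.671). The FSH-responsive call ended without Pik3cd-/- E2 replicate 3 (median 0.22, padj = 0.11) and Pik3cd-/- untreated replicate 2 (0.08, 0.249), the cell cycle call without Pik3cd-/- E2 replicate 2 (median 0.02, 0.0559), and the immediate early call without Pik3cd+/- E2 replicate 3 (0.0761). Panel genes did not pass. Fshr (0.31 ± 0.43), Inha (0.16 ± 0.17), Inhba (0.95 ± 0.93), Star (0.44 ± 0.79), Cyp11a1 (-0.86 ± 0.65), Cyp17a1 (-0.98 ± 0.86), Esr1 (0.02 ± 0.33) and Esr2 (-0.29 ± 0.22) had padj from 0.765 (Esr2) to 0.993 (Esr1). Pgr (-0.0015 ± 0.83), Amh (-0.02 ± 0.19), Gdf9 (0.39 ± 0.23), Kitl (0.31 ± 0.20), Kit (0.15 ± 0.29), Foxo1 (-0.08 ± 0.22), Foxo3 (-0.25 ± 0.12) and Igf1 (-0.35 ± 0.28) had padj from 0.688 (Foxo3) to 1.000 (Pgr).

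The study named as Pik3cd-dependent those target genes of Pik3cd+/- ovaries that did not change the same way in Pik3cd-/- ovaries, taken here as lacking a 2-fold change in the same direction. After PMSG, 194 targets (125 higher, 69 lower) divided into 50 that changed at least 2-fold the same way and 144 dependent genes, 79 higher and 65 lower. Of the 144 genes, 135 had the same sign in Pik3cd-/- ovaries, 18 were called there, and 0 changed 2-fold the opposite way. Their median change was 1.12 in Pik3cd+/- and 0.49 in Pik3cd-/- in the direction of the Pik3cd+/- change. None passed the interaction test in limma, and 61 had an unadjusted p under 0.05. Of the 194 targets, 15 passed with p adjusted over them alone, which is not independent evidence since they were chosen on these arrays. After E2, 37 targets gave 1 shared and 36 dependent genes, 31 with the same sign and 0 called in Pik3cd-/-. Of the 36, 0 passed the interaction test and 26 had an unadjusted p under 0.05, with medians of 1.22 and 0.30. Adjusted over the 37 targets, 20 passed. The count of 36 was 14 without Pik3cd+/- E2 replicate 2 and 7 without Pik3cd+/- untreated replicate 3. Itih2 changed by 1.65 ± 0.27 in Pik3cd+/- and -0.46 ± 0.27 in Pik3cd-/- ovaries, and Fgd5 by 1.37 ± 0.26 and -0.20 ± 0.26. Applied in reverse, from targets of Pik3cd-/- ovaries, the rule gave 14 dependent of 53 targets after PMSG and 1 of 2 after E2.

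**Figure D5:**
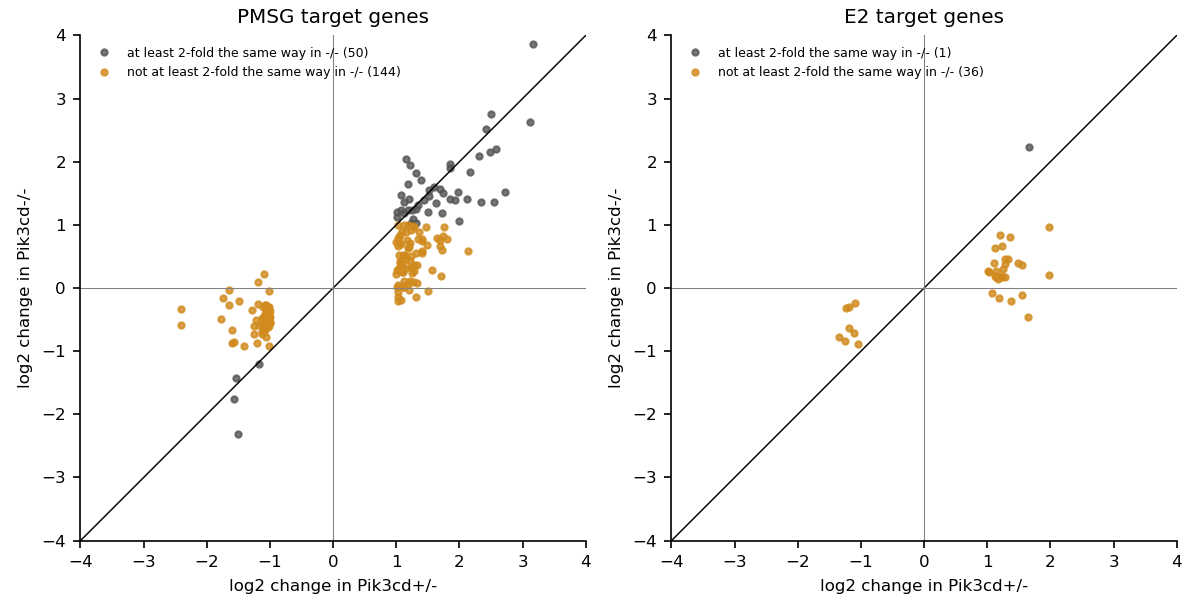
Log2 change of the PMSG (left) and E2 (right) target genes in Pik3cd+/- ovaries (horizontal axis) and in Pik3cd-/- ovaries (vertical axis); each point is a gene, and the line marks equal change. Of the 144 PMSG genes not changed at least 2-fold the same way in Pik3cd-/-, 135 lay on the same side of 0 in both genotypes.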

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

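The tests of oocyte share, other cell types, single arrays and macrophages below were chosen after the results were seen. Groups of 3 arrays were not tested for outliers. Results stand here because a set test of the difference between the genotypes' responses passed, or because a signal lay in probe sets that the comparisons did not use.

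The response of the oocyte list to treatment was less negative in Pik3cd-/- than in Pik3cd+/- ovaries, by a median of 0.39 for PMSG and 0.30 for E2 (0.15 to 0.60 with 1 array left out; padj = 0.752 and 0.591 with an estimated correlation), and the list was higher in Pik3cd-/- ovaries in each state. The genotype difference in the oocyte list exceeded that in the stromal, smooth muscle and endothelial lists by 0.80 (95% interval 0.405 to 1.19, exact permutation p = 0.00025, the smallest 8000 relabellings can give). This argues only against a lower granulosa share that raises all other cell types alike. The surface epithelium list was higher too (0.39, 95% interval 0.099 to 0.684), at 0.86 (0.638 to 1.09) for the oocyte list. Adipocyte (0.37, -0.724 to 1.46), macrophage (0.23, -0.253 to 0.708) and preantral granulosa lists (-0.11, -0.238 to 0.009) did not pass (permutation p = 0.537, 0.334 and 0.0665). The oocyte difference did not rest on 1 array: the lowest median of the list in any state was 0.52, without untreated Pik3cd-/- replicate 2, with an adjusted p of up to 1.3e-14 (preset correlation). Of the 30 members, 30 were higher on average and 29 lay within 0.5 of the list's median of 0.85, a bound chosen after the quartiles of 0.69 and 1.03 were seen, so this count decides nothing on a larger share of oocyte RNA, which stays open. Oocytes and follicles were not counted here, and the average difference had no camera call with an estimated correlation (padj = 0.236).

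The interferon list rose less after treatment in Pik3cd-/- ovaries, by a median of -0.41 for PMSG (-0.18 without Pik3cd-/- PMSG replicate 2 and -0.28 without Pik3cd+/- untreated replicate 3, padj = 0.177 and 0.0713) and -1.08 for E2, and neither call held with an estimated correlation (padj = 0.752 and 0.591). Its median rise after E2 in Pik3cd+/- ovaries was 1.10 or more without any 1 array, but each named gene lost its call in such fits. Pik3cd+/- E2 ovaries exceeded untreated Pik3cd-/- ovaries by 1.20 in the interferon list (95% interval 0.512 to 1.89) at a macrophage difference of -0.07 (-0.926 to 0.786), an interval too wide to exclude more macrophages. No other explanation was tested.

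For PMSG, the response also differed as a set in macrophage (-0.69), smooth muscle (-0.45), FoxO target (-0.38), cell cycle (0.35), immediate early (-0.34), surface epithelium (-0.31), LH-responsive (-0.24) and preantral granulosa genes (0.23). For E2 it differed in smooth muscle (-0.59), FSH-responsive (0.26), immediate early (-0.25), FoxO target (-0.23) and cell cycle genes (0.10). With an estimated correlation the adjusted p of these lists, oocyte and interferon genes included, was 0.138 or more. Without Pik3cd-/- untreated replicate 2 and Pik3cd-/- E2 replicates 2 and 3, the FSH-responsive difference for E2 was called in the opposite direction (-0.48, padj = 0.0341), the cell cycle median turned negative (-0.07), and those of smooth muscle (-0.16, padj = 0.332) and FoxO target genes (-0.09, 0.156) lost their call. Pik3cd-/- E2 replicate 2 had a smooth muscle mean of 9.31 against 10.35 and 10.34 in its mates, and without it that difference was -0.25 (padj = 0.0481).

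Among probe sets not used for genes, 353 of 1651 with no gene symbol (21.4%) and 150 of 600 with several symbols (25%) were called by limma in at least 1 of the 7 comparisons of 2 groups, against 6057 of 21553 with 1 symbol (28.1%).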

How the results depend on the processing

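Leaving out 3 arrays together and the replicate block with only the groups of the comparison were tests chosen after the results were seen, as was the average genotype difference; the others were planned. Named calls kept their side of the threshold in 197 cases against 2 that ended with a pseudocount of 1, 196 against 3 with one of 64, 193 against 6 each with quantile normalization and without trend, 190 against 9 with the probe set of highest variance and 183 against 16 with the replicate block. They were 178 against 0 with the stricter filter, 181 against 18 with no filter, 132 against 50 with only the groups of the comparison, 178 against 21 without 3 arrays and 1027 against 369 with 1 array left out; no called gene reversed. Of 83 list calls made with the preset correlation, an estimated one ended 79, the stricter filter 8 (immediate early genes for the average genotype difference and for that after E2 among them, padj = 0.0539 and 0.0762), quantile normalization 5, the probe set of highest variance 4, no filter 3, while a pseudocount of 64 ended 2 and one of 1 ended 0. The replicate block ended 5 (adjusted p of 0.0505 to 0.0550): FSH-responsive, immediate early and basal lamina genes for E2 in Pik3cd-/-, oestrogen targets for PMSG in Pik3cd-/- and surface epithelium genes for the PMSG interaction. Leaving out 3 arrays ended or reversed 12.

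With 1 array left out, called genes ran from 870 to 2410 for PMSG in Pik3cd+/- (2254), 82 to 383 in Pik3cd-/- (301), 33 to 110 for E2 in Pik3cd+/- (205) and 2 to 24 in Pik3cd-/- (7). Genotype differences ran from 1 to 677 untreated (277), 82 to 384 after PMSG (526) and 647 to 2968 after E2 (2139), and interactions from 0 to 4 for PMSG and 0 to 71 for E2. The study's rule gave 100 to 183 genes for PMSG (144) and 7 to 46 for E2 (36), and the average genotype difference 2653 to 3958 (3517). Fewer arrays lower the power of each such fit.

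Other settings moved counts by more than 1.5 times. With only the groups of the comparison they were 771 for E2 in Pik3cd+/- and 0 in Pik3cd-/-, 95, 991 and 100 for the genotype difference untreated, after PMSG and after E2, and 1 for the E2 interaction. Quantile normalization gave 484 for PMSG and 3 for E2 in Pik3cd-/-, 425 for the untreated genotype difference and 3 for the PMSG interaction, and took the share lower in the genotype difference after E2 to 56.2% and in the average genotype difference from 57.3% to 49.4%. The block gave 2 for E2 in Pik3cd-/- and 1 for the E2 interaction, and with only the PMSG groups 1067 for the genotype difference. For E2 in Pik3cd-/-, no filter gave 2 and the probe set of highest variance 16. A pseudocount of 64, which shrinks changes of dim genes, gave 62 and 19 genes under the study's rule for PMSG and E2 and 2 for the PMSG interaction, and a 2-fold change with no test 75 for E2. Except for the pseudocount, the cause was not tested.

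Without untreated Pik3cd-/- replicate 2 and Pik3cd-/- E2 replicates 2 and 3, which leaves replicate 1 alone for its group and assumed to vary like the others, the counts were 1005 and 4 for E2 in Pik3cd+/- and Pik3cd-/-, 174 and 1257 for the genotype difference untreated and after PMSG, 10 and 51 for the PMSG and E2 interactions and 57 for the study's rule for E2. The share lower was 52.7% for E2 in Pik3cd+/-, 39.1% and 45.3% for the genotype difference untreated and after E2 and 48.2% for the average. Directions reversed for PMSG in Pik3cd-/- Foxo1 (-0.0053) and Pgr (-0.17), for E2 in Pik3cd-/- oocyte genes (0.081), FSH-responsive genes (-0.46), Ccnd2 (-0.061), Esr2 (-0.39), Foxo1 (-0.29), Fshr (-0.44), Gdf9 (0.12), Inha (-0.15), Inhba (-1.24), Kit (0.014), Kitl (0.33) and Ooep (0.049), for the PMSG interaction Esr1 (0.014), Foxo1 (-0.0027) and Inhba (-0.30), for the E2 interaction cell cycle genes (-0.065), FSH-responsive genes (-0.48), Fshr (-0.29), Inha (-0.17), Inhba (-0.99) and Pgr (0.28). Under the other settings, Amh for the E2 interaction (0.049, quantile normalization), Ccnd2 for PMSG in Pik3cd-/- (-0.034, highest-variance probe set), Foxo3 for E2 in Pik3cd+/- (-0.047, highest-variance probe set; -0.011, quantile normalization), Igf1 for PMSG in Pik3cd-/- (-0.045, highest-variance probe set), and Pgr for the E2 interaction (0.11, pseudocount 64; 0.061, quantile normalization) reversed. The cause was not tested.

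With 1 array left out, named genes not past the threshold reversed in 69 of their fits, and lists past it in 2, oocyte genes for E2 in Pik3cd-/- (-0.46 to 0.023) and stromal fibroblast genes for E2 in Pik3cd-/- (-0.50 to -0.014), whose test turned while the median stayed negative. The genes for PMSG in Pik3cd+/- were Foxo1 (-0.024 to 0.014), Igf1 (-0.20 to 0.16), Inha (-0.19 to 0.0081) and Kitl (-0.11 to 0.0062). For PMSG in Pik3cd-/- these were Foxo1 (-0.013 to 0.28), Igf1 (-0.062 to 0.11) and Pgr (-0.17 to 0.29). For E2 in Pik3cd+/- these were Amh (-0.27 to 0.0032), Foxo3 (-0.048 to 0.046), Fshr (-0.37 to 0.0070) and Igf1 (-0.077 to 0.22). For E2 in Pik3cd-/- these were Esr2 (-0.11 to 0.20), Fshr (-0.022 to 0.37), Gdf9 (-0.38 to 0.049), Inhba (-0.34 to 1.35), Kit (-0.32 to 0.032) and Star (-0.0059 to 0.30). For the PMSG interaction these were Cyp11a1 (-0.076 to 0.70), Esr1 (-0.25 to 0.21), Foxo1 (-0.010 to 0.28), Igf1 (-0.14 to 0.22), Inhba (-0.30 to 1.39) and Star (-1.04 to 0.61). For the E2 interaction these were Amh (-0.17 to 0.096), Esr1 (-0.16 to 0.27), Foxo1 (-0.21 to 0.11), Inha (-0.012 to 0.26), Inhba (-0.092 to 1.60) and Pgr (-0.58 to 0.81). Medians of called lists also moved by over 1.5 times: for PMSG in Pik3cd+/- glycolysis (0.21 to 0.42), luteal (0.36 to 1.18) and proteases and inhibitors (0.12 to 0.28), for PMSG in Pik3cd-/- FSH-responsive granulosa (0.32 to 0.82) and oestrogen target (0.0071 to 0.11), for E2 in Pik3cd+/- cell cycle (-0.12 to -0.064), cholesterol synthesis (-0.23 to -0.11), FoxO target (0.10 to 0.16), glycolysis (0.075 to 0.19), oviduct (-0.90 to -0.38), stromal fibroblast (-0.12 to -0.059) and theca and steroidogenic (-0.27 to -0.11), for E2 in Pik3cd-/- basal lamina (-0.37 to -0.11), FSH-responsive granulosa (-0.068 to 0.33) and immediate early (0.026 to 0.22), for the genotype difference untreated cell cycle (-0.39 to -0.18) and smooth muscle (0.22 to 0.42), for that after PMSG glycolysis (-0.23 to -0.091) and interferon response (-0.73 to -0.16), for that after E2 surface epithelium (0.12 to 0.70), for the PMSG interaction immediate early (-0.52 to -0.22), interferon response (-0.71 to -0.18) and surface epithelium (-0.44 to -0.20) and for the E2 interaction cell cycle (0.019 to 0.23), FoxO target (-0.30 to -0.099), FSH-responsive granulosa (0.083 to 0.39), immediate early (-0.32 to -0.16), oocyte (0.15 to 0.60) and smooth muscle (-0.78 to -0.25). Each range is that of the log2 value over the arrays left out.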

Other observations

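The average genotype difference, the reading of MHC class II genes and the share of targets were tests chosen after the results were seen; the other counts of splits and the test of genes next to Pik3cd were planned.

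Averaged over the 3 states, genes higher in Pik3cd-/- ovaries included Ddx4 (1.29 ± 0.09, padj = 2.8e-06), Mael (1.36 ± 0.15, padj = 3.0e-05), Sycp3 (1.32 ± 0.15, padj = 4.6e-05) and Pln (1.42 ± 0.18, padj = 9.8e-05). Lower were Rgs13 (-1.69 ± 0.29, padj = 8.6e-04), Slc38a5 (-1.67 ± 0.26, padj = 4.3e-04), Fos (-1.55 ± 0.15, padj = 1.2e-05), Myf5 (-1.44 ± 0.15, padj = 1.8e-05), Tdgf1 (-1.39 ± 0.22, padj = 4.7e-04), Asb4 (-1.37 ± 0.10, padj = 2.8e-06), Grb14 (-1.29 ± 0.14, padj = 2.4e-05) and Tex14 (-1.29 ± 0.19, padj = 3.0e-04). Of MHC class II genes, H2-Aa was higher by 1.29 ± 0.22, Cd74 by 1.10 ± 0.21, H2-Ab1 by 1.02 ± 0.18, H2-Eb1 by 0.97 ± 0.19 and H2-DMa by 0.36 ± 0.11 (padj = 7.2e-04, 0.00161, 9.7e-04, 0.0016 and 0.0208). After PMSG alone the first 4 did not pass (H2-Aa 0.56, Cd74 0.59, H2-Ab1 0.50 and H2-Eb1 0.39, padj = 0.492, 0.448, 0.445 and 0.590). The macrophage list was higher untreated (0.58, padj = 1.3e-04) but did not pass after PMSG (-0.12, 0.451), after E2 (0.09, 0.306) or on average (0.20, 0.0831). These genes also differ between mouse strains, and the background was mixed. Neither macrophage share nor strain was tested for them. The calls of these 17 genes were kept with any 1 array left out (adjusted p of up to 0.0436, H2-DMa), and that of H2-DMa ended without 3 arrays (0.17, padj = 0.107). All 30 oocyte genes tested were higher (median 0.85, camera padj = 1.7e-29; padj = 0.236 with an estimated correlation), as were 3 of 10 surface epithelium genes (0.35, 0.0050; 0.691). Lower were 6 of 11 immediate early (-0.37, 0.0041; 0.313), 8 of 15 glycolysis (-0.20, 0.0041; 0.623), 5 of 12 LH-responsive (-0.24, 0.039; 0.236) and 4 of 10 interferon genes (-0.46, 0.039; 0.967). Limma called 3517 genes, 1501 higher and 2016 lower, with 27 and 33 at least 2-fold. Of the 3517, 539 had no overlap between the genotypes in any state and the same direction in all 3, which being called favours. The LH-responsive call ended without Pik3cd-/- E2 replicates 1 and 2 (0.0526 and 0.0513), Pik3cd-/- PMSG replicate 1 (0.0575), Pik3cd-/- untreated replicate 2 (0.0695), Pik3cd+/- E2 replicate 3 (0.102) and Pik3cd+/- untreated replicate 3 (0.0756). The interferon call ended without Pik3cd-/- PMSG replicates 2 and 3 (0.0619 and 0.0509), Pik3cd-/- untreated replicate 3 (0.0614), Pik3cd+/- E2 replicate 3 (0.102) and Pik3cd+/- PMSG replicate 1 (0.0655).

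Of 100 draws of genotype labels within each treatment, the real one gave 3517 genes and the others 0. For the average difference this argues against chance, not causes tied to genotype. Under the study's rule, 6 of 100 draws gave as many PMSG genes as the real 144 (highest other 398, median 24) and 2 of 100 as many E2 genes as the real 36 (highest other 39). These counts decide nothing on chance, since the draws left a median of 59 PMSG and 1 E2 targets against the real 194 and 37. The share of targets called dependent was 74.2% for PMSG against a median of 40% over the draws (5 of 99 as high). For E2 it was 97.3% against 85.7% (13 of the 56 with targets). The shares decide nothing either, for the same reason. For the interactions the real count was 0, so 100 of 100 draws gave as many; the highest other counts were 826 for PMSG, in the draw that also gave the 398 and exchanged the labels of all 6 untreated arrays, 0 PMSG arrays and 4 E2 arrays, and 2 for E2. At an unadjusted p under 0.05, 10 draws gave as many genes as the real 1196 for PMSG (highest other 2878) and 31 as many as the real 923 for E2 (2781). Exchanged untreated labels add genotype differences to the contrast (826 genes), so the draws decide nothing on chance for the interactions.

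For the 7 comparisons of 2 groups, 10 splits are too few for a share under 0.05. The real counts and the highest of the others were 2254 and 1 for PMSG in Pik3cd+/-, 301 and 0 in Pik3cd-/-, 205 and 1 for E2 in Pik3cd+/-, and 277 and 0, 526 and 11, and 2139 and 2 for the genotype difference untreated, after PMSG and after E2, each reached by 1 split. For E2 in Pik3cd-/-, 3 splits gave 7 genes or more, and the highest other gave 38; at an unadjusted p under 0.05, 3 gave as many as the real 1862 (highest other 2061). The genes next to Pik3cd gave an odds ratio of 0.83 (95% interval 0.478 to 1.37) of being called. It was 0.785 and 0.910 for 100 and 400 genes on each side. No excess of calls near the locus was seen, and linked variants acting on distant genes were not tested.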
